A study of Mus musculus with 12 samples.

How the data were processed

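RNA was sequenced from B16F10 and 4T1 cells with and without decitabine, 3 libraries per group and 12 in all. Per the labels' protocols, libraries were made with a kit that offers molecular indices, and cells were freed of dead cells with microbeads. Whether the indices were used in counting is not given in the sources used here. The series' design text names 2 kinds of Illumina instrument without saying which library ran on which, so that an instrument difference cannot be tested. The deposited tables hold estimated counts per gene, 1 table per line, and the values are not scaled between libraries. RSEM and edgeR are named without versions or roles in the submitters' processing notes, with the genome build mm10. The aligner, the gene annotation, the filters and the strand setting are not given in the sources used here.

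The tables held 46517 genes, of which 46005 matched the GENCODE M21 annotation of the same build by identifier. 27 symbols altered by a spreadsheet were restored from their identifiers, and a repeated identifier was resolved for Sipa1l2. In all 12 libraries 17458 genes had 0 counts. Between 9.5% and 15.5% of the entries of a library were not whole numbers. The estimated counts were rounded to whole numbers for the tests. Library totals ranged from 48197936 to 76042600 counts. Intervals and lower bounds cover counting error only, since reads without molecular indices are not independent molecules.

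Groups were taken from the labels. Each line was tested on its own 6 libraries with edgeR 4.0.16 (quasi-likelihood fit and test, robust) in R 4.3.3, after the default expression filter and TMM scaling, with Benjamini-Hochberg adjustment and a threshold of 0.05. The difference between the responses was tested as a contrast in one fit of all 12 libraries. Standard errors were derived from the log2 fold change and the test statistic. CPM values are scaled with the TMM factors, and shares of a library are not. Of each line's libraries, the biological coefficient of variation was 10.5% in B16F10 and 6.92% in 4T1. The smallest chi-square per degree of freedom between 2 libraries of a group was 5.67, so that no pair agreed within sampling noise. Dose differs between the lines together with the line, 0.1 µM and 1 µM, so neither can be separated from the other.

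There were 32 gene lists, fixed before the data were examined, as were the tests of genes and of lists, the rule for named genes and all alternatives but the one named last below. Some tests in the closing section were chosen after their results had been seen, and are named there. Lists with at least 5 tested genes were tested with camera (limma 3.58.1) at a preset correlation between genes of 0.01. The correlation estimated from the data was used as an alternative, as was fry, which tests whether a list's genes move one way and does not compare the list with other genes. A fold against a group with 0 counts is given as a lower bound against 3 counts over the 3 libraries of the group. With 1 to 3 counts the ratio is given with its 95% counting interval. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15. Sequence shared between genes was measured as the percentage of a gene's 31-base words that occur in another gene's transcripts, from a sample of 1 in 4 words.

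Named genes were chosen per line as the 10 largest increases and the 10 largest decreases among genes past the threshold with a mean of at least 2 CPM in the higher group, no overlap between the groups' libraries, which chance gives in 10% of genes with 3 against 3, and an official symbol. Names of predicted genes were excluded by the rule, and clone names, which the rule did not list, were read as not official symbols after seeing the data. Some genes that the rule names are not reported here. Dnmt1, Dnmt3a, Dnmt3b and Uhrf1 are always given. Each list adds up to 2 rising and 2 falling members with the smallest adjusted p. For genes changed in both lines the 10 largest increases and 5 largest decreases are named, and for the difference between the lines the 6 genes per direction with the smallest adjusted p.

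The tests were tried on simulated counts made from the real control means, library sizes and dispersions with 200 genes changed. The changed genes were drawn from genes above a minimum mean count and changed in either direction. In the B16F10 simulation (13451 genes) the test recovered 70% of genes changed 1.5-fold, 82% at 2-fold, 98% at 4-fold and 100% at 16-fold. In the 4T1 simulation (13800 genes) it recovered 78%, 90%, 100% and 100%, and in that of the difference between the lines (15453 genes) 64%, 66%, 80% and 98%. Of the calls, 6.42%, 8.91% and 6.67% were genes that had not been changed. A list raised 1.5-fold was called in both lines, and the 1 other list called in each shared members with it. Genes were simulated independently of one another, so this does not show how the list test does with correlated genes. In the data 41.2% of tested genes were called in B16F10 and 75.3% in 4T1. The simulated rates, with few genes changed, need not hold there.

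Alternatives were DESeq2 1.42.0, limma-voom, relative log expression scaling, library size only, other count filters, a replicate block, one fit of all libraries, counts not rounded and each library left out in turn. A fit without genes that share at least 5% of their 31-base words with at least 10 other genes was added after seeing the data.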

Results

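RNA was sequenced from 2 mouse tumour cell lines grown with or without decitabine, a cytidine analogue that is incorporated into DNA and traps DNA methyltransferases. B16F10 is a melanoma line and 4T1 is a mammary carcinoma line. B16F10 cells received 0.1 µM and 4T1 cells 1 µM for 48 h, and dead cells were removed before RNA was taken. Each of the 4 groups had 3 libraries, 12 in all. The libraries held 48197936 to 76042600 estimated counts. At these depths, 3 counts correspond to 0.0395 to 0.0622 CPM (counts scaled by library size) per library. The labels do not say whether the 3 replicates of a group were separate cultures, so p-values measure the spread between these samples, which may be technical.

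Decitabine-treated libraries held counts for more genes than the controls in both lines. B16F10 libraries held 17540 ± 217 genes with an estimated count above 0 without the drug and 19500 ± 493 with it (SD, n = 3 each). The 4T1 libraries held 19670 ± 201 and 23380 ± 563 (SD, n = 3 each). The 10 most counted genes of each library took 8.82% ± 0.741 of the counts in B16F10 control and 10.1% ± 0.915 in B16F10 decitabine libraries (SD, n = 3 each). In 4T1 that share was 5.61% ± 0.19 in control and 23.2% ± 0.758 in decitabine libraries (SD, n = 3 each). The most counted gene there, RP24-390N7.1 on chromosome 5, named after its values were seen, took 5.57% ± 0.2 of the counts with decitabine and 0.32% ± 0.02 without (SD, n = 3 each).

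**Figure D1:**
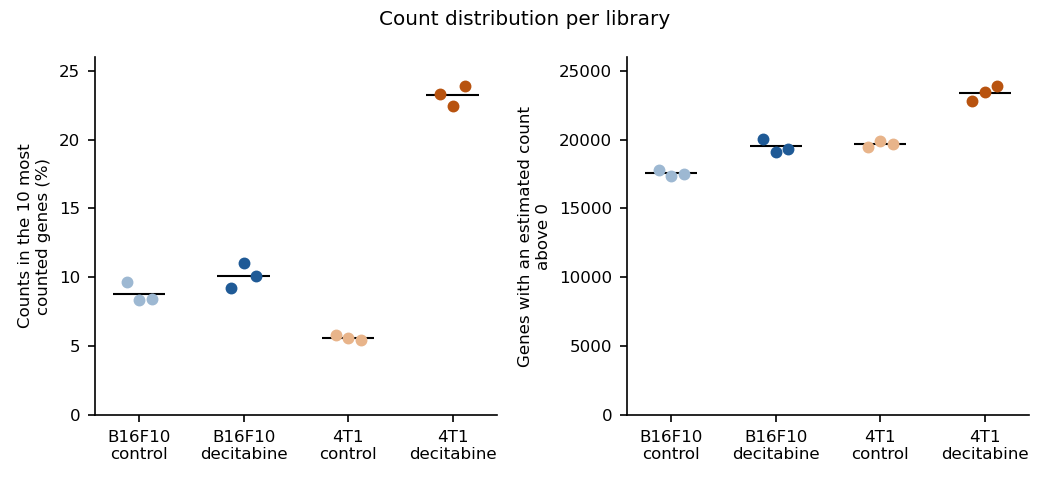
The share of all counts in each library's 10 most counted genes (left, percent) and the number of genes with an estimated count above 0 (right), with a point per library and a line at the group mean. The 3 libraries of 4T1 with decitabine lie between 22.42% and 23.93%, and those of the 4T1 control between 5.42% and 5.8%.

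The first comparison asked which transcripts changed with 0.1 µM decitabine in B16F10 melanoma cells. Genes normally transcribed in germ cells rose from near absence, interferon-stimulated genes and p53 target genes rose, and genes of DNA replication fell. Glycolysis genes fell too, though their list did not pass with an estimated correlation (adjusted p = 0.0725). With these groups moved immediate early and heat shock genes, a list fixed as a sign of RNA quality (17 of 26 higher), fibroblast markers (7 of 11 higher) and blood and immune markers (4 of 8 higher), though none of these 3 lists passed with an estimated correlation (adjusted p = 0.0807, 0.0807 and 0.291). The fibroblast and blood lists held 20 and 30 genes, and the count filter favours members that rise from near 0 counts. The median log2 fold change was 1.76 for interferon-stimulated genes, 1.08 for p53 target genes and -0.50 for both falling groups. Of 14344 tested genes, 3070 were higher and 2840 were lower with decitabine in edgeR's quasi-likelihood test at a Benjamini-Hochberg adjusted p under 0.05. Large changes were mostly increases. A change of at least 2-fold was found for 1195 higher and 116 lower genes, and one of at least 16-fold for 367 higher genes and 1 lower gene, Gm2260, named after its values were seen. Of the higher genes, 150 had 0 counts in all 3 control libraries. Lists for which no other numbers are given had the same numbers higher and lower when adjusted over the list alone.

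The target of the drug itself was lower in B16F10. Dnmt1, the maintenance DNA methyltransferase (ENSMUSG00000004099, mm10 chromosome 9, 20907209 to 20959888), fell from 306 ± 11.8 to 194 ± 8.48 CPM (SD, n = 3 each), a log2 fold change of -0.66 (SE 0.0563, adjusted p = 2.57e-08). Uhrf1, which recruits Dnmt1 to replicated DNA, fell from 247 to 173 CPM (adjusted p = 5.26e-07). The de novo methyltransferase gene Dnmt3a rose from 115 to 177 CPM (adjusted p = 4.99e-08), while Dnmt3b read 9.61 and 9.66 CPM (adjusted p = 0.962). Across the DNA methylation machinery, 4 of 21 tested genes were higher and 11 were lower, and the same numbers held when adjusted over the list alone. The list as a whole did not pass camera, a test of a list against all other genes (adjusted p = 0.189). Among genes of deoxycytidine uptake and metabolism, 5 of 17 were higher and 7 were lower (adjusted p = 0.0542, or 0.0279 without control replicate 1, 0.0396 without decitabine replicate 1 and 0.0482 without decitabine replicate 3). In that list Tk1, thymidine kinase, fell from 104 to 50.1 CPM, and Dut, which removes dUTP, fell from 57.5 to 35.6 CPM.

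Germline genes showed the largest increases in B16F10. Of 34 tested genes on the list of germline genes known to be silenced by promoter methylation, 28 rose and 1 fell, and the same numbers held when adjusted over the list alone. The median log2 fold change was 6.50, or 5.08 with genes absent from the control libraries set at their lower bound (camera adjusted p = 1.51e-25, and adjusted p = 0.00894 with an estimated correlation). Tex19.1 (ENSMUSG00000039329, chromosome 11, 121146143 to 121148319), which acts in germ cells and placenta, had 1 count over the 3 control libraries and 1698 over the 3 decitabine libraries, a ratio of 1728 with a 95% counting interval of 310 to 68310. Tex101, a germ cell surface protein gene, rose from 1.16 to 15.8 CPM. Mov10l1, a piRNA-pathway helicase, Rec8, a meiotic cohesin subunit, and Sohlh2, a germ cell transcription factor, had 0 control counts and were at least 134-fold, 130-fold and 121-fold higher. The falling member was Zcwpw1, from 130 to 90.3 CPM. Of the X-linked germline families Mage, Xlr and Rhox, 16 of 18 tested genes rose and 1 fell, also when adjusted over the list alone, with a median of 5.54, or 4.69 at the bound (adjusted p = 1.36e-18, and adjusted p = 0.0128 with an estimated correlation). This list and that of germline genes silenced by promoter methylation held 53 genes each, of which 18 and 34 were tested. The count filter favours members that rise from near 0 counts, so the numbers risen do not describe the whole lists. Nxf3 rose from 0.147 to 6.52 CPM. Rhox2a and Rhox2f were at least 253-fold and 153-fold higher, and Xlr3a fell from 20.7 to 16.6 CPM. Dppa4 and Dppa2, early embryo genes on the pluripotency and cleavage-stage list, were at least 217-fold and 65.1-fold higher. On that list 7 of 14 tested genes rose and 1 fell (adjusted p = 0.000775, and adjusted p = 0.0758 with an estimated correlation). It held 35 genes, and the same limit of the count filter applies to it. The other largest increases were those of AI481877, Lilra6 and Kcns3, at least 218-fold, 219-fold and 164-fold higher. Rhox2a, Rhox2f, Xlr3a, Lilra6, Dppa4 and Dppa2 share between 32.3% and 96.2% of their 31-base words with other annotated genes, so that their counts are uncertain.

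Interferon-stimulated genes rose in B16F10. Of 63 tested interferon-stimulated genes, 57 rose and 0 fell, also when adjusted over the list alone, with a median log2 fold change of 1.76 (adjusted p = 1.37e-42, and adjusted p = 0.013 with an estimated correlation). Ifit1 (ENSMUSG00000034459, chromosome 19, 34640871 to 34650009), an antiviral RNA-binding protein gene, rose from 10.2 ± 0.176 to 103 ± 6.51 CPM (SD, n = 3 each), a log2 fold change of 3.33 (SE 0.0707, adjusted p = 1.42e-16). Irgm1, an interferon-induced GTPase gene, rose from 25.7 to 78.4 CPM. Of 25 tested nucleic acid sensing genes, 12 rose and 0 fell (adjusted p = 3.09e-05, and adjusted p = 0.0403 with an estimated correlation). The median log2 fold change of this list was 0.227. It shares members with the interferon-stimulated list, among them Ddx58 and Dhx58, so it is not a separate result. Ddx58, which encodes the RNA sensor RIG-I, rose from 16.8 to 59.9 CPM and its relative Dhx58 from 0.799 to 7.47 CPM. In MHC class I antigen presentation, 14 of 19 tested genes rose and 0 fell (adjusted p = 3.45e-05, and adjusted p = 0.0403 with an estimated correlation), among them Tapbp, from 22.3 to 60.1 CPM, and Calr, from 1176 to 1793 CPM. Chemokine and cytokine genes rose in 10 and fell in 3 of 23 cases (adjusted p = 7.37e-05, and adjusted p = 0.0725 with an estimated correlation). Ccl5 rose from 0.392 to 4.35 CPM and Lif from 2.69 to 12.0 CPM, while Vegfa fell from 57.3 to 33.5 CPM. Of 17 checkpoint and NK ligand genes, 8 rose and 2 fell (adjusted p = 0.00699, and adjusted p = 0.122 with an estimated correlation). Lgals9 rose from 46.8 to 97.4 CPM and Cd47, a signal against phagocytosis, fell from 56.5 to 37.2 CPM. NF-kB target genes rose in 10 and fell in 2 of 17 cases, or 11 and 2 adjusted over the list alone (adjusted p = 0.00699, and adjusted p = 0.248 with an estimated correlation), with Csf1 rising from 18.7 to 36.4 CPM. MHC class II genes numbered 5, of which 2 rose (adjusted p = 0.185), Cd74 from 0.406 to 2.78 CPM.

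The p53 target genes rose and DNA replication and S phase genes fell in B16F10. Of 43 tested p53 target genes, 34 rose and 1 fell, or 34 and 2 adjusted over the list alone, Fdxr being the falling gene, with a median log2 fold change of 1.08 (adjusted p = 1.24e-55, and adjusted p = 0.00894 with an estimated correlation). Btg2, an antiproliferative gene, rose from 11.1 ± 0.758 to 75.6 ± 3.68 CPM (SD, n = 3 each), a log2 fold change of 2.76 (SE 0.0708, adjusted p = 1.07e-15). In the list of death receptors, caspases and gasdermins, 18 of 36 genes rose and 4 fell, or 22 and 5 adjusted over the list alone (adjusted p = 0.0102, and adjusted p = 0.0758 with an estimated correlation). This list shares members with the p53 target list, among them Tnfrsf10b and Fas. The death receptor gene Tnfrsf10b rose from 9.20 to 23.1 CPM. Fas, another death receptor gene, had 1 control count and 301 decitabine counts, a ratio of 306 with a 95% counting interval of 54.6 to 12140. Of 57 DNA replication and S phase genes, 53 fell and 1, Ccne1, rose, or 54 and 2 adjusted over the list alone (median -0.50, adjusted p = 1.94e-22, and adjusted p = 0.0164 with an estimated correlation). Rad51ap1, a recombination factor gene, fell from 102 to 50.4 CPM and Pold1, a DNA polymerase subunit gene, from 115 to 60.6 CPM. G2 and M phase genes fell in 34 and rose in 3 of 44 cases, or 36 and 3 adjusted over the list alone (adjusted p = 5.13e-07, and adjusted p = 0.0651 with an estimated correlation), with Top2a falling from 835 to 552 CPM and Cdc20 rising from 73.0 to 122 CPM. Of 38 Fanconi anaemia and double-strand break repair genes, 24 fell and 2 rose, or 26 and 3 adjusted over the list alone (adjusted p = 1.43e-09, and adjusted p = 0.0758 with an estimated correlation). Bard1, the partner of Brca1, fell from 40.3 to 20.5 CPM. The rising members were Nbn and Rad51d, the latter with an adjusted p of 0.0442 that became 0.0506 with limma-voom, 0.0932 with library size only, 0.0665 with no filter and 0.0674 with a replicate block, and was between 0.0635 and 0.194 without control replicate 1 or 2 or decitabine replicate 1 or 2.

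Metabolic and stress genes were examined next in B16F10. Of 30 hypoxia and glycolysis genes, 27 fell and 1 rose, also when adjusted over the list alone (median -0.50, adjusted p = 1.31e-14, and adjusted p = 0.0725 with an estimated correlation). Pdk1, which restrains pyruvate oxidation, fell from 66.4 to 22.8 CPM and Bnip3, a mitophagy gene, from 78.6 to 29.2 CPM, while Aldoc, an aldolase gene, rose from 0.915 to 3.62 CPM. The list of the integrated stress response and unfolded protein response had 16 members higher and 18 lower among 40 fixed genes, 39 of them tested. Its median was 0.01 and its mean -0.08, and camera placed it lower (adjusted p = 0.000216, and adjusted p = 0.122 with an estimated correlation). The falling members included the amino acid response genes Trib3, from 155 to 41.8 CPM, Chac1, from 59.2 to 16.8 CPM, Pck2, from 126 to 39.3 CPM, and Mthfd2, from 320 to 136 CPM. The rising members included the endoplasmic reticulum genes Hspa5, from 668 to 1322 CPM, and Syvn1, from 60.1 to 115 CPM. Other genes with the largest decreases were Akr1b7, Tspan18, Nupr1, Gpt2, Kirrel3 and Cth, with log2 fold changes from -2.30 to -1.50. Of 32 cholesterol and fatty acid synthesis genes, 8 rose and 7 fell (adjusted p = 0.434).

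Lineage and other cell type markers were examined as well in B16F10. Of 28 melanocyte lineage genes, 9 rose and 11 fell, or 9 and 14 adjusted over the list alone (adjusted p = 0.326). Kit, a receptor of melanocyte precursors, rose from 0.0254 to 2.71 CPM, and Rab38, a melanosome gene, fell from 514 to 284 CPM. Epithelial and mammary genes rose in 7 and fell in 1 of 16 cases (adjusted p = 0.00164, and adjusted p = 0.0807 with an estimated correlation), with the milk protein gene Csn3 rising from 0.0469 to 4.30 CPM. Extracellular matrix and mesenchymal genes rose in 22 and fell in 1 of 33 cases, or 23 and 1 adjusted over the list alone (adjusted p = 3.14e-07, and adjusted p = 0.0725 with an estimated correlation), Sparc from 715 to 1222 CPM. The falling gene was Col4a2 (adjusted p = 0.0152, or 0.0737 without B16F10 control replicate 1). Fibroblast markers rose in 7 and fell in 2 of 11 cases (adjusted p = 0.00322, and adjusted p = 0.0807 with an estimated correlation). Blood and immune markers rose in 4 of 8 cases (adjusted p = 0.0432, and adjusted p = 0.291 with an estimated correlation, 0.0898 without B16F10 control replicate 1, 0.0605 without decitabine replicate 2 and 0.0601 without decitabine replicate 3). The immune markers included Cd68, which was already at 99.5 CPM in the control. Of 4 endothelial markers tested, 2 rose, Mmrn2 from 0.0329 to 6.20 CPM and Eng from 167 to 242 CPM. The epithelial, fibroblast, blood and endothelial lists held 48, 20, 30 and 18 genes. The count filter favours members that rise from near 0 counts, so the numbers risen do not describe the whole lists. Of 2135 tested genes with a control mean under 0.5 CPM in B16F10, 848 were higher. Mitochondrial transcripts rose in 4 of 15 cases (adjusted p = 0.102, or 0.0414 with a replicate block, 0.00769 without control replicate 1 and 0.0266 without decitabine replicate 1) and took 7.0% ± 0.912 of the control and 8.76% ± 1.13 of the decitabine counts (SD, n = 3 each). Immediate early and heat shock genes rose in 17 and fell in 1 of 26 cases (adjusted p = 2.9e-06, and adjusted p = 0.0807 with an estimated correlation). The falling gene was Ier2 (adjusted p = 0.0322, or 0.0769 to 0.159 without control replicate 2 or 3 or decitabine replicate 1 or 2, and 0.49 in one fit of all 12 libraries). Imprinted genes rose in 15 and fell in 6 of 33 cases, or 16 and 6 adjusted over the list alone (adjusted p = 0.127, or 0.0352 with a replicate block).

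The second comparison asked the same question for 1 µM decitabine in 4T1 mammary carcinoma cells. Germline genes, interferon-stimulated genes and MHC class I genes rose. Histone genes rose too, and genes of cholesterol synthesis and glycolysis fell, though these 3 lists did not pass with an estimated correlation (adjusted p = 0.161, 0.248 and 0.372). The histone list (54 of 59 higher) and that of immediate early and heat shock genes (18 of 27 higher) were fixed as signs of RNA quality, and both moved with decitabine in 4T1, the latter without passing at an estimated correlation (adjusted p = 0.333). With these groups also rose markers of blood and immune cells (9 of 10), fibroblasts (7 of 9) and endothelium (8 of 11). These marker lists held 30, 20 and 18 genes, and the count filter favours members that rise from near 0 counts. Of 3131 tested genes with a control mean under 0.5 CPM in 4T1, 2386 were higher. The endothelial list did not pass camera (adjusted p = 0.0848), and the blood and fibroblast lists did not pass with an estimated correlation (adjusted p = 0.161 and 0.261). The median log2 fold change was 3.25 for interferon-stimulated genes and -1.60 for cholesterol and fatty acid synthesis. Of 15523 tested genes, 6087 were higher and 5601 were lower (edgeR, adjusted p under 0.05), 52.1% of the calls being higher. A change of at least 2-fold was found for 3258 higher and 864 lower genes, and one of at least 16-fold for 1024 higher and 12 lower genes. Of the higher genes, 285 had 0 counts in all 3 control libraries. With library size alone as the scale, the split was 4248 higher and 8242 lower, or 34% higher, the median of all genes moved from 0.03 to -0.27, and 282 genes were called in the opposite direction. Directions of small changes in 4T1 are therefore relative to the scaling.

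In 4T1, Dnmt1 fell from 387 ± 23.7 to 319 ± 12.4 CPM (SD, n = 3 each), a log2 fold change of -0.28 (SE 0.0523, adjusted p = 0.000515), and Uhrf1 fell from 282 to 204 CPM (adjusted p = 3.14e-05). Dnmt3b fell from 5.10 to 4.12 CPM (adjusted p = 0.0121, or 0.0506 without 4T1 decitabine replicate 2). Dnmt3a read 16.7 and 18.5 CPM (adjusted p = 0.382, or 0.0183 without 4T1 control replicate 1). Of 22 DNA methylation machinery genes, 5 rose and 13 fell (adjusted p = 0.167). Gadd45g, a stress-inducible demethylation cofactor gene, rose from 4.43 to 49.1 CPM, and Tet3, a 5-methylcytosine oxidase gene, fell from 53.2 to 23.4 CPM. Among 18 genes of deoxycytidine uptake and metabolism, 6 rose and 9 fell (adjusted p = 0.769). Cmpk2, a mitochondrial nucleotide kinase gene that interferon also induces, rose from 1.20 to 54.8 CPM, and Tk1 fell from 153 to 50.3 CPM.

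The largest increases in 4T1 were again those of germline genes. Of 37 tested genes on the list of germline genes silenced by promoter methylation, 35 rose and 2 fell, also when adjusted over the list alone, with a median log2 fold change of 10.50, or 8.67 at the bound (adjusted p = 5.28e-74, and adjusted p = 0.0134 with an estimated correlation). Dazl (ENSMUSG00000010592, chromosome 17, 50279395 to 50293636), a translation regulator of germ cells, had 1 control count and 19710 decitabine counts, a ratio of 20290 with a 95% counting interval of 3641 to 801300. Ddx4, the germ cell helicase gene, had 1 and 7978 counts, a ratio of 8212 with an interval of 1473 to 324400. Tdrd1, Hormad1, Tex11 and Fkbp6, which act in meiosis or the piRNA pathway, had 0 control counts and were at least 1114-fold, 1111-fold, 1090-fold and 792-fold higher. Igsf10, Cyp4a12b and D1Pas1 were at least 1281-fold, 1053-fold and 939-fold higher, and the testis tubulin gene Tuba3b had a ratio of 13030 with an interval of 2338 to 514600. The falling members were Cpne8, from 46.7 to 35.8 CPM (adjusted p = 5.71e-05, or 0.0575 in one fit of all libraries), and Spo11, from 0.589 to 0.267 CPM. Mage, Xlr and Rhox genes rose in 27 of 28 cases, also when adjusted over the list alone (median 8.45, or 6.24 at the bound, adjusted p = 5.41e-12, and adjusted p = 0.0379 with an estimated correlation), Rhox5 from 1.01 to 25.95 CPM. The Mage, Xlr and Rhox list and that of germline genes silenced by promoter methylation held 53 genes each, of which 28 and 37 were tested. Here too the count filter favours members that rise from near 0 counts, so the numbers risen do not describe the whole lists. Pluripotency and cleavage-stage genes rose in 14 and fell in 1 of 16 cases (adjusted p = 0.00884, and adjusted p = 0.233 with an estimated correlation). That list held 35 genes, and the same limit of the count filter applies to it. Imprinted genes rose in 17 and fell in 17 of 35 cases (adjusted p = 0.6), Cdkn1c, a cell cycle inhibitor gene, from 0.0286 to 6.18 CPM. Cyp4a12b, Tuba3b and Hormad1 share 61.5%, 46.7% and 36.0% of their 31-base words with other genes and Igsf10 overlaps Med12l, so that their counts are uncertain.

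Interferon-stimulated genes rose almost throughout in 4T1, in the same libraries as the histone genes (54 of 59) and the blood and immune markers (9 of 10). Of 84 tested genes, 83 rose and 0 fell, also when adjusted over the list alone, with a median log2 fold change of 3.25 (adjusted p = 1.91e-91, and adjusted p = 0.00731 with an estimated correlation). Ddx58 rose from 42.3 ± 0.643 to 312 ± 1.27 CPM (SD, n = 3 each), a log2 fold change of 2.88 (SE 0.0401, adjusted p = 1.17e-12). Irf9, a transcription factor of the interferon response, rose from 5.57 to 74.6 CPM. The interferon gene Ifnb1 itself had 3 control counts and 1484 decitabine counts, a ratio of 509 with a 95% counting interval of 174 to 2472. Nucleic acid sensing genes rose in 14 and fell in 4 of 25 cases (adjusted p = 4.75e-08, and adjusted p = 0.0379 with an estimated correlation). This list shares members with the interferon-stimulated list, among them Ddx58 and Irf7. Irf7, the transcription factor that amplifies interferon production, rose from 1.23 to 61.5 CPM, and the adaptor gene Mavs fell from 27.7 to 18.6 CPM. MHC class I genes rose in 26 and fell in 1 of 30 cases (adjusted p = 3.1e-10, and adjusted p = 0.0183 with an estimated correlation), H2-T23 from 15.9 to 58.1 CPM, and the falling gene was Erap1. Chemokine and cytokine genes rose in 28 and fell in 11 of 42 cases (adjusted p = 0.000126, and adjusted p = 0.0772 with an estimated correlation), with Cxcl11 rising from 0.261 to 7.56 CPM and Il34 falling from 13.6 to 5.05 CPM. Of 29 NF-kB target genes, 23 rose and 6 fell (adjusted p = 0.00345, and adjusted p = 0.123 with an estimated correlation), Tnf from 0.469 to 8.91 CPM. Checkpoint and NK ligand genes rose in 15 and fell in 6 of 25 cases (adjusted p = 0.0848, or 0.0373 without repeat-sharing genes, a fit chosen after the data were seen). Cd274, which encodes PD-L1, rose from 1.45 to 18.9 CPM, and Nt5e, an adenosine-producing ectoenzyme gene, fell from 88.0 to 33.8 CPM. MHC class II genes numbered 5, of which 3 rose and 1 fell (adjusted p = 0.75). The fall was that of Lgmn, whose adjusted p of 0.0498 became 0.0556 to 0.283 with DESeq2, relative log expression scaling, a stricter count filter, a replicate block or the removal of repeat-sharing genes, and 0.0805 to 0.167 without control replicate 2 or 3 or decitabine replicate 2 or 3.

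Death, p53 and cell cycle genes moved in both directions in 4T1. Of 44 p53 target genes, 26 rose and 10 fell (adjusted p = 0.128). Trp53, the gene of p53 itself, rose from 38.5 to 85.2 CPM and Apaf1, the apoptosome scaffold gene, fell from 40.5 to 20.5 CPM. Of 39 death receptor, caspase and gasdermin genes, 15 rose and 17 fell (adjusted p = 0.373). Ripk3, the necroptosis kinase gene, had 0 control counts and was at least 371-fold higher. Bcl2, an inhibitor of apoptosis, fell from 35.1 to 11 CPM. DNA replication and S phase genes fell in 32 and rose in 13 of 57 cases (adjusted p = 0.0257, and adjusted p = 0.694 with an estimated correlation, or 0.105 with a stricter count filter). Fanconi anaemia and double-strand break repair genes fell in 24 and rose in 5 of 38 cases (adjusted p = 0.00884, and adjusted p = 0.161 with an estimated correlation). In that list H2afx fell from 91.5 to 53.3 CPM. Chek1 and Nbn rose by 0.25 each on the log2 scale, but with library size alone as the scale their values were -0.048 and -0.046 and neither passed. G2 and M phase genes fell in 22 and rose in 7 of 44 cases (adjusted p = 0.129, or 0.0115 with library size only).

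Lipid and glycolysis genes were examined next in 4T1. Of 32 cholesterol and fatty acid synthesis genes, 31 fell and 0 rose, also when adjusted over the list alone (median -1.60, adjusted p = 1.98e-18, and adjusted p = 0.248 with an estimated correlation). Elovl6 (ENSMUSG00000041220, chromosome 3, 129532355 to 129638495), a fatty acid elongase gene, fell from 174 ± 8.49 to 32.6 ± 0.807 CPM (SD, n = 3 each), a log2 fold change of -2.41 (SE 0.0485, adjusted p = 1.56e-11). Fdps, an isoprenoid synthase gene, fell from 253 to 61.7 CPM. Of 30 hypoxia and glycolysis genes, 25 fell and 2 rose (median -1.04, adjusted p = 2.85e-06, and adjusted p = 0.372 with an estimated correlation). Ldha, lactate dehydrogenase, fell from 1579 to 681 CPM. The rising members were Slc16a3 and Vegfa. Vegfa rose from 20.4 to 37.8 CPM (adjusted p = 0.0107, or 0.0504 with library size only). In the integrated stress response and unfolded protein response list, 24 of 40 genes rose and 10 fell (adjusted p = 0.0108, and adjusted p = 0.123 with an estimated correlation, or 0.0561 with library size only). Atf3, a stress transcription factor, rose from 9.74 to 284 CPM, and the serine synthesis gene Psat1 fell from 475 to 342 CPM. Other genes with the largest decreases were Aldoc, Bnip3, Rgs11, Adamts9, Trib2, Etv1 and the protocadherin genes Pcdhb21, Pcdhb17 and Pcdhb22, with log2 fold changes from -4.18 to -2.97. Zbed6 had 0 counts with decitabine and was at least 210-fold lower, but all of its sampled 31-base words occur in other annotated genes and it overlaps Zc3h11a, so that its count is uncertain.

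Identity and other cell type markers in 4T1 moved as follows. Epithelial and mammary genes rose in 19 and fell in 16 of 46 cases (adjusted p = 0.167). Krt17, a basal keratin gene, rose from 0.514 to 78.8 CPM, and Gata3, a luminal transcription factor gene, fell from 83.0 to 40.0 CPM. Extracellular matrix and mesenchymal genes rose in 24 and fell in 14 of 43 cases (adjusted p = 0.753), Col1a2 rising from 0.206 to 5.27 CPM and S100a4 falling from 365 to 149 CPM. Melanocyte lineage genes rose in 6 and fell in 5 of 14 cases (adjusted p = 0.6). Blood and immune markers rose in 9 and fell in 1 of 10 cases (adjusted p = 0.00819, and adjusted p = 0.161 with an estimated correlation), Csf1r from 0.917 to 12.4 CPM. The falling marker was Cd14 (adjusted p = 0.0423, or 0.0651 to 0.143 when a library other than control replicate 3 or decitabine replicate 2 was left out, and 0.0519 to 0.12 with DESeq2, relative log expression scaling, a stricter count filter, a replicate block or one fit of all libraries). Fibroblast markers rose in 7 and fell in 1 of 9 cases (adjusted p = 0.0352, and adjusted p = 0.261 with an estimated correlation, 0.0566 without 4T1 control replicate 1 and 0.0517 without 4T1 decitabine replicate 3). Endothelial markers rose in 8 of 11 cases (adjusted p = 0.0848, or 0.0401 with library size only), Cdh5 from 0.282 to 8.13 CPM. The blood, fibroblast and endothelial lists held 30, 20 and 18 genes, and the count filter favours members that rise, so the numbers risen do not describe the whole lists. Replication-dependent histone genes, whose mRNAs usually lack a poly(A) tail, rose in 54 of 59 cases (median 2.92, adjusted p = 8.55e-10, and adjusted p = 0.161 with an estimated correlation), Hist1h2bc from 2.16 to 67.6 CPM. In B16F10 these rose in 6 and fell in 1 of 33 cases, or 4 and 1 adjusted over the list alone (adjusted p = 0.327, or 0.00614 with a stricter count filter). Immediate early and heat shock genes rose in 18 and fell in 2 of 27 cases in 4T1 (adjusted p = 0.00111, and adjusted p = 0.333 with an estimated correlation).

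**Figure D2:**
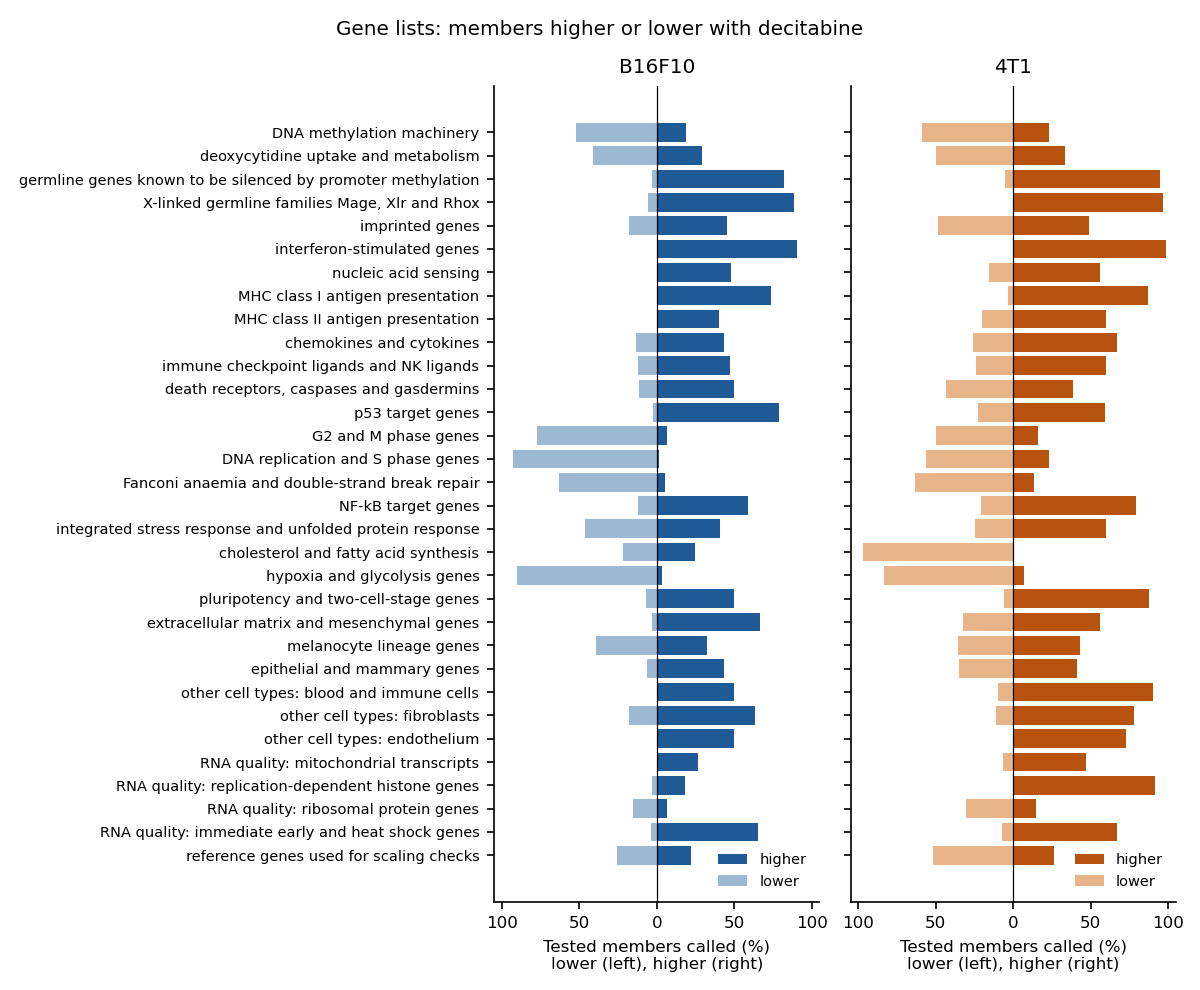
The percentage of tested members of each gene list that were higher (right of 0) or lower (left of 0) with decitabine in B16F10 and in 4T1 at an adjusted p under 0.05. Of the interferon-stimulated genes, 57 of 63 were higher in B16F10 and 83 of 84 in 4T1, and of the cholesterol and fatty acid synthesis genes 31 of 32 were lower in 4T1.

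The lines were then compared for genes that changed in both. Among 12946 genes tested in both lines, 1452 were higher in both, where 933 were expected from independent calls (Fisher's exact test, odds ratio 2.77, p = 7.58e-118), and 1588 were lower in both, where 1090 were expected (odds ratio 2.59, p = 7.18e-105). Another 749 were higher in B16F10 and lower in 4T1 (1096 expected), and 496 were lower in B16F10 and higher in 4T1 (928 expected). The p-values of Fisher's exact test treat genes as independent replicates, which they are not, and do not measure the spread between libraries. With library size alone as the scale, 976 were higher in both and 2363 lower in both. Across genes, which are not independent replicates, the log2 fold changes had a Pearson r of 0.534 and a Spearman rho of 0.305. The shared increases were led by the germline genes Rhox2a, Tex19.1, Sohlh2, Tuba3b, Tuba3a, Taf7l and Mov10l1, with AI481877, Slc47a1 and Xist. Xist, the noncoding RNA of X inactivation (chromosome X, 103460366 to 103483254), rose from 0.405 ± 0.175 to 61.7 ± 4.92 CPM in B16F10 and from 0.116 ± 0.0315 to 168 ± 7.07 CPM in 4T1 (SD, n = 3 each). It overlaps its antisense gene Tsix, and the strand used in counting is not given in the sources used here, so that their counts cannot be told apart. Taf7l rose from 0.024 to 5.98 CPM in B16F10 and from 0.0342 to 74.0 CPM in 4T1. The shared decreases were led by Pdk1, Tenm4, Bnip3, Efcab11 and Ankrd37. Pdk1 fell from 66.4 to 22.8 CPM in B16F10 and from 55.7 to 11.1 CPM in 4T1. Ankrd37 fell with an adjusted p of 0.0464 in 4T1, a call lost with no count filter and without any of the 3 decitabine libraries of that line.

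**Figure D3:**
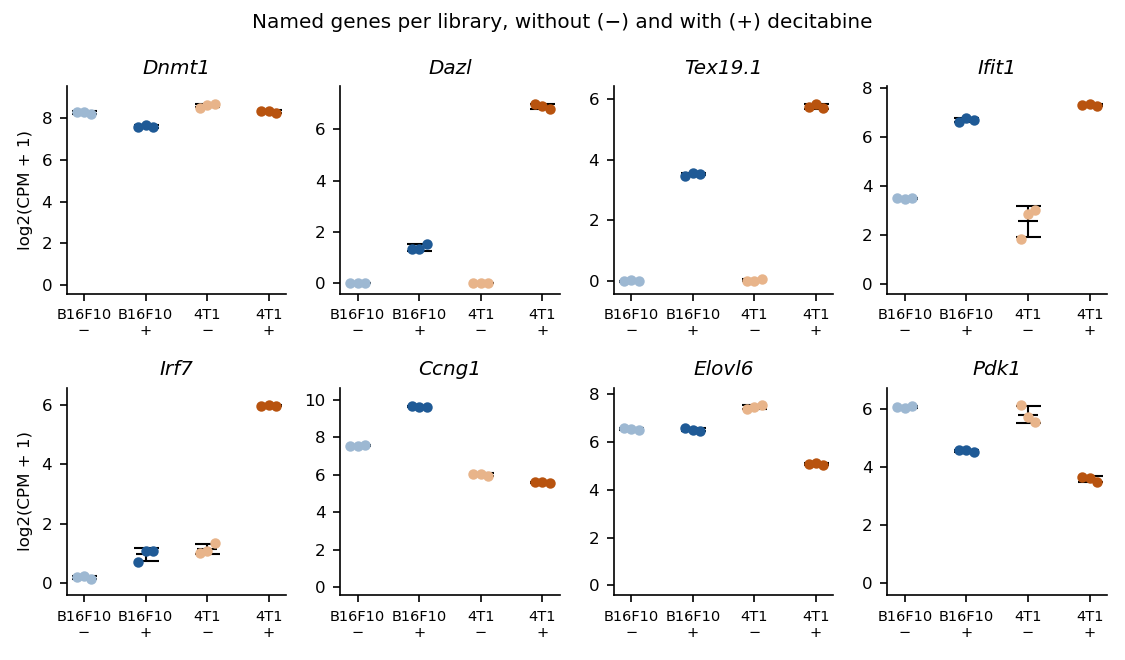
Values of 8 genes in each library as log2(CPM + 1), with a point per library and bars for the mean and SD of the 3 libraries, for both lines without and with decitabine. Ccng1 was higher with decitabine in B16F10 and lower in 4T1, and Elovl6 was lower in 4T1 and read 91.9 and 90.2 CPM in B16F10 (adjusted p = 0.759), the 8 genes having been chosen after their values were seen.

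The last comparison tested the difference between the responses of the lines itself, which differ in line and dose together. Of 17127 genes tested in one fit of all 12 libraries, 4949 had a more positive response in B16F10 and 3577 in 4T1. With library size alone as the scale these were 6908 and 2475. Ccnd1, the cyclin D1 gene, rose from 84.3 to 263 CPM in B16F10 and fell from 1186 to 420 CPM in 4T1, a log2 difference of 3.18 (SE 0.0728, adjusted p = 6.96e-16). Ccng1, a p53 target gene, rose from 187 to 796 CPM in B16F10 and fell from 63.9 to 47.2 CPM in 4T1. Hmga2, a chromatin protein gene, rose from 32.2 to 67.3 CPM in B16F10 and fell from 278 to 88.5 CPM in 4T1, and Sorbs2 and Celf2 likewise rose in B16F10 and fell in 4T1. Piwil2, a piRNA-pathway gene, was at 138 CPM in B16F10 control and 137 CPM with decitabine, while in 4T1 it rose from 0.0692 to 29.9 CPM. Fkbp6 read 246 and 248 CPM in B16F10 and rose from 0 counts to 13.7 CPM in 4T1. Aebp1 and Arhgap30 did not pass in B16F10, and Neto2 rose there from 48.8 to 61.8 CPM, while all 3 rose in 4T1, Neto2 from 1 count to 2884, a ratio of 2969 with a 95% counting interval of 532 to 117300. Rab3gap1 rose from 315 to 1071 CPM in B16F10 and from 474 to 17650 CPM in 4T1, and its count is uncertain because it shares sequence with other highly counted genes. Lists with a more positive response in B16F10 included those of cholesterol and fatty acid synthesis (median difference 1.82, adjusted p = 2.32e-23, and adjusted p = 0.139 with an estimated correlation) and of p53 target genes (0.70, adjusted p = 7.61e-06, and adjusted p = 0.0404 with an estimated correlation). Lists with a more positive response in 4T1 included interferon-stimulated genes (-1.28, adjusted p = 5.59e-12, and adjusted p = 0.0495 with an estimated correlation) and the germline genes silenced by promoter methylation (fitted median -3.61, not a bound, with 15 of 41 more positive in 4T1 and 3 in B16F10, adjusted p = 0.000141, and adjusted p = 0.0488 with an estimated correlation).

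Some named genes share sequence with other annotated genes or overlap them, which leaves their counts uncertain. Uhrf1, Tapbp, Cdc20, Bnip3, Hist1h2bc, S100a4, Cxcl11, H2-T23, Cdkn1c, Fdps, Akr1b7 and Tuba3a share between 25.4% and 56.3% of their 31-base words with another gene, and Ccnd1 and Ankrd37 23.2% and 22.4%. Tk1, Cdc20, Tapbp, Eng, Syvn1, Zcwpw1, Irf7, Irf9, Csf1r, Ccnd1, Rgs11, Ankrd37, Pcdhb21 and Pcdhb22 overlap other genes. So do Dnmt3a, Dnmt3b, Dhx58, Fas, Mov10l1, AI481877, Akr1b7, Kirrel3 and Cth, and further named genes may. Reads of overlapping genes cannot be assigned without the strand setting, which the sources used here do not give.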

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

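The tests of divided reads, of falls of at least 2-fold, of the scaling of the p53 list, and of summed and rescaled protocadherin counts were chosen after their results had been seen. The fit without repeat-sharing genes was also chosen after the data were seen. The results below are differences between the lines, tested as such, and dose and line differ together. More positive in B16F10 were 4949 genes and in 4T1 3577. Among 100 drawn splits of both lines' libraries, 2 gave as many as 4949 in a direction, the real one included, and 6 gave as many as 3577, the highest other being 5587. The share is under 0.05 for the first and above it for the second. Every drawn split with as many as 3577 genes kept the real grouping of at least 1 line and so its effect. Splits that keep neither grouping remove the effect of the drug from both lines. Neither share therefore tests the difference between the responses against chance. The split with 5587 kept both lines' real grouping with the labels of a line exchanged. In the 78 drawn splits that kept neither line's grouping, the highest count was 3.

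The genes with the clearest differences were Ccnd1 (log2 difference 3.18), Ccng1 (2.57), Hmga2 (2.77), Elovl6 (2.43), Sorbs2 (3.80) and Celf2 (1.88), more positive in B16F10. More positive in 4T1 were Piwil2 (-8.68), Aebp1 (-5.62), Arhgap30 (-5.70), Fkbp6 (-12.6), Rab3gap1 (-3.41) and Neto2 (-10.7). The differences of Fkbp6 and Neto2 are fitted values against 0 or 1 count and are not bounds.

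Of the gene lists, the median difference was 0.70 for p53 target genes, 1.82 for cholesterol and fatty acid synthesis, 0.572 for hypoxia and glycolysis (adjusted p = 0.0154, and adjusted p = 0.699 with an estimated correlation) and 0.336 for death receptors, caspases and gasdermins (adjusted p = 0.00124, and adjusted p = 0.0446 with an estimated correlation). The death receptor list shares members with the p53 target list. The median difference was -1.28 for interferon-stimulated genes. For germline genes silenced by promoter methylation the fitted median was -3.61, with 15 of 41 genes more positive in 4T1 and 3 in B16F10. For Mage, Xlr and Rhox genes it was -2.84, with 7 of 28 more positive in 4T1 and 0 in B16F10 (adjusted p = 0.00874, and adjusted p = 0.142 with an estimated correlation). Both medians include genes with 0 control counts and are not bounds. It was -0.0854 for G2 and M phase genes (adjusted p = 0.0439, and adjusted p = 0.547 with an estimated correlation) and -0.22 for DNA replication and S phase genes (adjusted p = 8.94e-05, and adjusted p = 0.523 with an estimated correlation). It was -0.483 for the integrated stress response and unfolded protein response (adjusted p = 1.6e-05, and adjusted p = 0.0495 with an estimated correlation) and -2.81 for replication-dependent histone genes, a list fixed as a sign of RNA quality (34 of 63 more positive in 4T1 and 1 in B16F10, adjusted p = 6.18e-07, and adjusted p = 0.0488 with an estimated correlation).

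The p53 target list responded more in B16F10. Low counts of the list in 4T1 are argued against, since the 31 members with a mean of at least 5 CPM in both lines had a median difference of 0.721, with 22 more positive in B16F10 and 3 in 4T1. A change of scale moves all genes alike and cannot make the list differ from them, by 0.653 with library size only, where all genes moved to 0.276 and the list to 0.928. For the size of the list's own difference scaling cannot be told apart, since against the 27 reference genes it was 0.558 with a 95% bootstrap interval of 0.0848 to 1.05, above 0 but not above the bound of 0.2. The bootstrap drew genes of both lists, not libraries, so the interval holds no spread between libraries. The dose, 10 times higher in 4T1, cannot be told apart from the line, and the biological difference between the lines stays open and untested.

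Genes that share sequence took a large share of the counts in 4T1 with decitabine: of the 10 most counted genes there, 9 shared over 5% of their 31-base words with the others, and 0 did so in the other 3 groups. Sharing was counted only within each group's own 10 genes. The 9 genes also took larger shares with decitabine in B16F10. There RP24-390N7.1 went from 0.25% to 0.85% and was among the 10 most counted with the drug. In 4T1 with decitabine, reads divided among genes go with the counts of the 9 sharing genes. Of these counts 100% were not whole numbers, against 66% in the next 100 most counted genes. Counts were not whole in all 3 libraries for all 9 of these genes and for 59 of the next 100 (one-sided Fisher's exact test on genes, p = 0.0116). A rise at these loci alone cannot be told apart from one of a repeat family: 18 other tested genes that carry the shared words had a median log2 fold change of 3.87 and 17 rose, but divided reads would raise them too, which the prediction overlooked. Lower counts of other genes as a mere result are argued against for falls of at least 2-fold, since the median of all genes was -0.272 with library size only. For smaller falls this cannot be told apart: 5450 genes were lower without the repeat-sharing genes, against 5601, but the scaling trims such genes already, which the prediction overlooked, and the median of all genes moved only from 0.0271 to 0.0309.

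Protocadherin beta genes on chromosome 18 (37264938 to 37524479) fell in 4T1, 12 of 12 tested, and in B16F10 5 of 21 fell and 1 rose. Reads moved between these genes are argued against, since their summed CPM fell from 21.8 ± 0.486 to 2.52 ± 0.26 (SD, n = 3 each), a log2 ratio of -3.11. Reads moved to other genes on the stretch are argued against by its total of -3.09, and scaling by a median of -3.08 relative to the reference genes. Of 21 genes in the test of the difference, 18 were more positive in B16F10 and 0 in 4T1. A loss of transcription across the cluster in 4T1, at its dose, stays open and untested.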

How the results depend on the processing

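The fit without repeat-sharing genes was chosen after seeing the data. Of the counts recomputed, 191 stayed within 1.5 times the reported count. The other 7 were counts of gene lists. With an estimated correlation between genes, camera called 6 lists higher and 1 lower in B16F10, against 16 and 5, and 5 higher and 0 lower in 4T1, against 13 and 4. With fry, 8 lists were lower in B16F10, and 21 were higher and 9 lower in 4T1. The cause was not tested for fry or for camera. Some lists that lost their call with camera had an estimated correlation above the preset 0.01, such as cholesterol and fatty acid synthesis in 4T1 (0.781). Others had one below it, such as death receptors, caspases and gasdermins in B16F10 (-0.0154) and the stress response list in 4T1 (-0.00259). A correlation above the preset does not account for the loss of the latter. Of named genes, 4608 of the values kept their side of the threshold, 61 lost it, 1 gained it and 2 reversed. These 2 were Chek1 in 4T1 (-0.048) and Nbn in 4T1 (-0.046) with library size only, whose median of all genes is -0.27, and neither passed. All 252 recomputed differences between the lines kept their direction and call. They belong to 12 genes chosen for the smallest adjusted p, so they do not show how stable the other calls are. Leaving out each library in turn gave 2695 to 3097 higher and 2374 to 2818 lower genes in B16F10, and 5803 to 6554 higher and 5257 to 5897 lower genes in 4T1. A replicate block gave 2947 higher and 2781 lower genes in B16F10, 5906 and 5401 in 4T1, and 4801 and 3379 for the difference between the lines. Libraries with the same number did not deviate together (paired correlations of -0.398, -0.381 and -0.00216 in B16F10 and -0.26, 0.198 and -0.225 in 4T1), so the numbers show no pairing. Between control and decitabine libraries of unlike number the correlations ran from -0.225 to 0.491 in B16F10 and from -0.303 to 0.329 in 4T1. A pairing or batch under other numbers therefore stays possible. Without repeat-sharing genes, 3046 genes were higher and 2784 lower in B16F10, 5977 and 5450 in 4T1, and the difference between the lines gave 4970 and 3347. For the 6 libraries of a line, 10 splits are too few for a share under 0.05. The real split called 3070 higher and 2840 lower genes in B16F10 and 6087 and 5601 in 4T1, and the highest other split called 0. For gene lists, 2 of the 10 splits gave as many as the 16 higher lists in B16F10 (highest other 16) and 10 as many as the 5 lower. In 4T1, 2 gave as many as the 13 higher (highest other 14) and 10 as many as the 4 lower. Every other split keeps 2 libraries of a group together, so that list directions partly remain in it. Of the 100 splits of both lines, 1, the real one, gave as many genes as the 1452 higher and the 1588 lower in both lines (highest other 749). Since every other split of a line called 0 genes, an overlap could arise only where both lines kept their real grouping or its mirror. The outcome was set by the effects within the lines, so it does not test the overlap against chance. Depth limits genes near 3 counts, 0.0395 to 0.0622 CPM.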

Other observations

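Genes that rose at least 16-fold lay on chromosome X more often than other tested genes. Of 367 such genes in B16F10, 63 lay on chromosome X, or 17.2%, against 3.65% of all tested genes (Fisher's exact test, odds ratio 6.08, 95% interval 4.48 to 8.13, p = 2.18e-25). In 4T1, 99 of 1024 lay there, or 9.67% against 3.3% (Fisher's exact test, odds ratio 3.65, p = 7.09e-23). Among genes with a control mean under 0.5 CPM alone, the odds ratios were 4.95 and 4.09. At that level the count filter favours genes that rise, so these ratios do not cover all silent genes. A hypothesis is that silent genes of chromosome X respond more often, and chance among the tested genes is argued against by the odds ratio of 6.08, though neighbouring genes of a family are not independent.

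Genes that rose at least 16-fold in 4T1 were looked up in B16F10. Of 442 such genes tested in B16F10, 142 rose at least 16-fold there too. Of 104 with a control mean of at least 5 CPM there, 21.2% rose at least 2-fold (median log2 fold change 0.137), where 1.28% of all B16F10 genes at that level did. Of 261 with a control mean under 0.5 CPM, 77.4% did (median 4.32), where 39.6% of all tested genes at that level did, a level at which the count filter favours genes that rise. The hypothesis that genes already transcribed are not raised further predicted under 20%, so that the value of 21.2% leaves it open by that rule. The rule took no account of the 1.28% of all genes at that level. With a share above that, the hypothesis does not hold for each of these 104 genes as counted. Among those that rose at least 2-fold is Rab3gap1, whose count is uncertain because it shares sequence with other highly counted genes. The share without such genes was not computed, so how far they carry the 21.2% stays open.

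Genes detected also rose in number when library totals were made equal. In 4T1 the 10 most counted genes took 23.2% of the decitabine and 5.61% of the control counts. The depth left for other genes there was therefore not equal. Thinned to 48197894 counts, the control libraries held 17293 to 17605 genes in B16F10 and 19369 to 19461 in 4T1, and the decitabine libraries 18907 to 19768 and 22662 to 22770. Of the genes at least 16-fold higher, 94% in B16F10 and 79% in 4T1 were protein-coding, where 86.3% and 86% of the tested genes were. In B16F10, the 19 tested genes that carry the shared words of the most counted 4T1 genes had a median log2 fold change of 1.44, and 11 rose and 0 fell.

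The ribosomal protein genes were lower for 12 and higher for 5 of 77 in B16F10 (adjusted p = 0.324) and lower for 25 and higher for 12 of 81 in 4T1 (adjusted p = 0.6). Adjusted over the list alone, the numbers in B16F10 were 5 lower and 5 higher. The germ cell paralogues Rps4l and Rpl39l rose in 4T1, Rps4l with 1 and 7317 counts, a ratio of 7531 with a 95% counting interval of 1351 to 297500, and Rpl39l with 0 control counts, at least 395-fold higher. Rps4l shares 29.7% of its 31-base words with other genes and overlaps Tmtc1, so that its count is uncertain. Mitochondrial transcripts rose in 7 and fell in 1, mt-Nd1, of 15 cases in 4T1 (adjusted p = 0.753). The reference genes used for scaling checks rose in 6 and fell in 7 of 27 cases in B16F10 (adjusted p = 0.611) and rose in 7 and fell in 14 in 4T1 (adjusted p = 0.128, or 0.0255 with library size only).

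For some lists that did not pass camera, the median, the mean and the direction of the test differed in sign. In B16F10 the melanocyte lineage genes had a median of -0.11 and a mean of 0.30, the ribosomal protein genes -0.08 and 0.16, with both tests pointing lower, and the reference genes 0.03 and -0.01. In 4T1 the genes of deoxycytidine uptake and metabolism had -0.22 and 0.52, the death receptor, caspase and gasdermin genes -0.09 and 0.47, the melanocyte lineage genes -0.09 and 0.42 and the ribosomal protein genes -0.04 and 0.33, with the test pointing lower. The imprinted genes in 4T1 had -0.06 and 1.18, with the test pointing higher.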
